A study of Mus musculus with 133 samples.

How the data were processed

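The series holds 133 hippocampus RNA libraries from mice of the AD-BXD panel, in which the 5XFAD line, carrying human APP with familial Alzheimer mutations under a Thy1 promoter, was crossed to inbred strains. Each library is labelled with genotype (5XFAD, or Ntg for non-transgenic), age (6 or 14 months), sex and strain. RNA was extracted by the authors with RNeasy kits on a QIAcube after DNase treatment, and stranded polyA libraries were sequenced as paired ends. The authors named Bowtie 1.1.2 and the mouse genome build mm10, and the deposited tables give transcripts per 1000000 (TPM), per gene and per isoform, with human rows added, of which the APP transcript is reported. Every column sums to 1000000 with the human rows included. No read counts were used here, so the sequencing depth of each library is unknown, no counting interval could be given, and the precision of each value rests on the spread between libraries alone.

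The gene table had 47645 rows, of which 47643 were mouse genes. Symbols and coordinates came from GENCODE M21 (GRCm38). For 16484 of 16832 tested genes that could be compared, the deposited gene value equalled the sum of its isoforms within 0.001 TPM in every library. Genes with a mean of at least 0.5 TPM over all libraries were tested, which left 16911 mouse genes, 16836 of them with a symbol. Values were analysed as log2(TPM + 1) in limma 3.58.1 (R 4.3.3), with a term for each of the 8 genotype, age and sex groups, a fixed term for each strain label and eBayes with trend. Benjamini-Hochberg adjusted p below 0.05 called a gene. The contrasts were 5XFAD minus Ntg at each age, 14 minus 6 months in each genotype, female minus male in each genotype, the genotype by age and genotype by sex interactions, and D2 minus B6. F tests covered the strain terms and, over the 14 strain labels with both genotypes, the strain by genotype terms. Errors of log2 differences are standard errors (SE), and errors of TPM means are standard deviations (SD). Adjusted p values of genes come from limma throughout.

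Fixed lists of marker and pathway genes, 27 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within each contrast, and again with an estimated correlation. The lists were activity-dependent genes, Alzheimer risk locus orthologues, antigen presentation, astrocyte, blood, cholesterol synthesis, choroid plexus, complement, disease-associated microglia, endothelial, excitatory neuron, hippocampal subfield, homeostatic microglia, inhibitory neuron, interferon response, lysosome, mural, oligodendrocyte and myelin, oligodendrocyte precursor, oxidative phosphorylation, peripheral myeloid, reactive astrocyte, striatum, synaptic, T cell and thalamus, and a list of X and Y genes for the sex check. A list score is the mean of log2(TPM + 1) over the measured members in a library. As the series text describes for its own by-strain work, libraries were averaged into strain, age, genotype and sex cells before strains were compared, then over the sexes. Differences among strains in the genotype effect on a score, and in human APP, were tested with an F statistic by permutation of residuals with 100000 resamples. Differences in human APP with genotype, sex and age were tested two-sided by permuting labels, also with 100000 resamples. For sex and age the labels were permuted within strain and the other of these factors. Correlations over strains were Pearson's r and Spearman's rho with permutation p, repeated without the 2 strains farthest from the median of the x measure, and adjusted over a family of 9. The smallest p that these permutations can give is 1e-05. Permutation tests, figures and by-strain values used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

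The groups, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names, for each contrast, the 10 genes with the largest and the 5 with the lowest log2 difference among called genes with a mean of at least 1 TPM and a symbol that is not a predicted model. It also names the 10 genes with the smallest p in an F test, members of the fixed lists (the 3 with the smallest p first), human APP, App, Thy1 and the sex genes. Some genes that this rule names are not reported here. The alternatives were pseudocounts of 0.1 and 0.5, a filter at 5 TPM or none, quantile and median-ratio scaling, isoform sums, choroid plexus and myelin scores as covariates, no strain term, strain as a random block (statmod 1.5.0, consensus correlation 0.0847), no B6 or D2 libraries, averaged cells, strain as the replicate, a single age, and leaving out each strain in turn. After the data were examined, alternatives without the 4 Ntg libraries with human APP or the 7 libraries that failed a transgene or sex check, median-ratio scaling for the gene lists, the 8 groups as terms for by-strain scores, removal of the sex difference before averaging for the correlations, and the transgene levels without those 7 were added. No library was left out of the main values. The method was tested on simulated data with independent noise for each gene and no strain effects. A change of 0.5 (log2) added to genes was called in 96% of them for the genotype at 14 months and in 94% for the genotype by age interaction. A change of 0.25 was called in 80% and 50%. Genes called in the real data had median sizes of 0.16 and 0.27 in these 2 contrasts. Counts of called genes were set beside 99 random regroupings of the libraries.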

Results

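Hippocampal RNA was measured in 133 libraries, 69 from 5XFAD and 64 from non-transgenic (Ntg) mice, 65 female and 68 male. The mice were killed straight after a test of contextual fear memory. At 14 months the 5XFAD group had 16 females and 20 males and the Ntg group 17 and 16. At 6 months there were 15 females and 18 males with the transgenes and 17 and 14 without. Of the 15 strain labels, D2 had 25 libraries, B6 had 18 and each of 13 numbered strains had fewer. Between 14882 and 15839 genes per library reached 1 TPM (median 15243), and the 10 most abundant genes took 12.4% to 24.5% of the TPM. Pairwise correlations over genes between libraries ran from 0.930 to 0.991, and no pair was identical. The depth is unknown because TPM alone were used here. The panel was built to ask how genetic background, age and sex alter the hippocampal response to the 5XFAD transgenes.

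The human APP transcript averaged 1825 ± 510 TPM (SD, n = 69) in 5XFAD and 9.26 ± 34.7 TPM (n = 64) in Ntg libraries (permutation p = 1e-05, the smallest the test can give). The Ntg mean was 5.99 TPM without its highest library and 1.08 ± 1.01 TPM (n = 60) without the 4 Ntg libraries with human APP. Among 5XFAD libraries, females carried more human APP than males, 2051 ± 562 (n = 31) against 1641 ± 380 TPM (n = 38), a ratio of 1.25 (permutation p = 3e-05). Human APP was also higher at 14 than at 6 months, 1950 ± 549 (n = 36) against 1689 ± 433 TPM (n = 33, permutation p = 0.00878). This age difference did not pass without the B6 and D2 libraries (permutation p = 0.707). Strain labels did not differ detectably in human APP (F = 1.08, permutation p = 0.398), with means from 1557 TPM in D2 to 2278 TPM in strain 77.

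**Figure D1:**
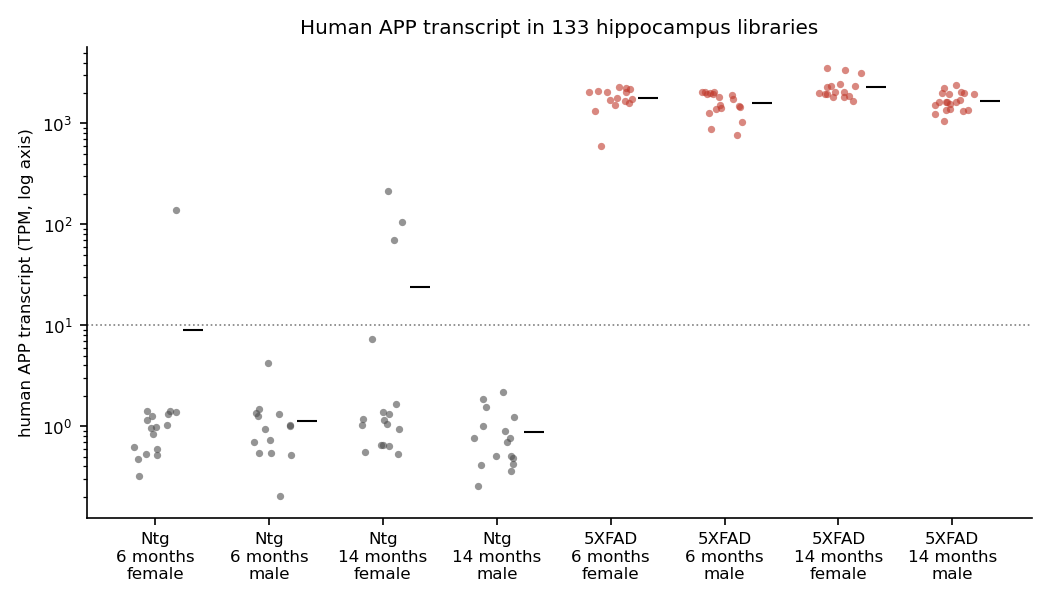
Human APP transcript in each of 133 libraries (points, TPM on a log axis) by genotype, age and sex, with short bars at group means and a dotted line at 10 TPM. The lowest 5XFAD library has 590 TPM, and 4 Ntg libraries, all female, lie between 69.7 and 215.1 TPM above the line.

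Mouse rows that share sequence with the transgene construct moved as well. Mouse App fell by 0.18 ± 0.03 on the log2 scale (SE, adjusted p = 1.53e-08) at 14 months and by 0.09 at 6 months (adjusted p = 0.0195). Human reads placed on its row would raise it. How reads were divided between the mouse and human rows was not tested, so the fall may not reflect less mouse transcript. Thy1, whose promoter drives the transgene, rose by 1.72 ± 0.05 and 1.67 ± 0.05, from 776 ± 49.8 to 2550 ± 385 TPM at 14 months, and reads of the construct can be part of this rise.

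At 14 months the genotype difference was led by genes of activated microglia. Cst7, a lysosomal protease inhibitor, averaged 143 ± 38.2 TPM (SD, n = 36) in 5XFAD and 1.31 ± 3.88 TPM (n = 33) in Ntg hippocampus, a log2 difference of 6.32 ± 0.22 (SE, adjusted p = 1.88e-51). Without its highest library the Ntg mean of Cst7 was 0.637 ± 0.469 TPM. Trem2, the microglial lipid receptor, rose from 20.5 ± 3.43 to 167.1 ± 31.2 TPM (2.95 ± 0.09, adjusted p = 6.45e-57). Its signalling adaptor Tyrobp rose from 47.2 ± 8.60 to 340 ± 56.7 TPM. The astrocyte filament gene Gfap rose from 279 ± 54.8 to 1620 ± 605 TPM (2.51 ± 0.11), and Apoe, the main lipid carrier of the brain, from 3023 ± 253 to 5716 ± 693 TPM (0.92 ± 0.04). After Cst7 the largest rises were those of the integrin gene Itgax (3.73 ± 0.12), the glucan receptor gene Clec7a (3.69 ± 0.12), the class II chaperone gene Cd74 (3.55 ± 0.23) and the class II gene H2-Aa (3.13 ± 0.20). Trem2 came next, then lysozyme Lyz2 (2.91 ± 0.13), osteopontin Spp1 (2.89 ± 0.16), the chemokine gene Ccl3 (2.87 ± 0.10) and Cd52 (2.83 ± 0.12). Adjusted p among these 10 ran up to 1.52e-27. The lowest differences were smaller. Ndst4, a heparan sulfate enzyme, went from 11.2 ± 1.58 to 6.17 ± 1.63 TPM (-0.83 ± 0.06, adjusted p = 3.28e-23) and the interneuron peptide gene Cort from 13.6 ± 4.53 to 8.53 ± 3.98 TPM (-0.70 ± 0.09). Kirrel2 (-0.61 ± 0.07), the lipoxygenase gene Alox12b (-0.59 ± 0.06) and the pseudogene row Ptges3-ps (-0.83 ± 0.31, adjusted p = 0.0197) completed the lowest 5. On GRCm38, Cst7 (ENSMUSG00000068129) lies on chromosome 2 from 150570415 to 150578944 and Trem2 (ENSMUSG00000023992) on chromosome 17 from 48346401 to 48354147. Ndst4 (ENSMUSG00000027971) lies on chromosome 3 from 125404076 to 125728899. In all, 7867 of 16911 genes passed, 2686 higher and 5181 lower in 5XFAD. Of these, 245 of the higher and 1 of the lower changed more than 2-fold. This cut, here and at 6 months, was applied to log2(TPM + 1), which limits how far genes of low TPM can fall but not rise. Part of that asymmetry can therefore come from the pseudocount. The balance of higher and lower calls moved with the scaling, since median-ratio scaling gave 3346 higher and 3702 lower.

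Microglial, immune and astrocyte lists rose at 14 months, some whole and others in part (a single count means that adjustment over the list alone gave the same). Of 29 disease-associated microglia genes 28 rose, Tyrobp (2.82 ± 0.09), Trem2 and Itgax having the smallest p (list median 1.96, camera adjusted p = 1.45e-62). Homeostatic microglia genes did not fall as a group. Of these 16 genes, 14 rose, among them Gpr34 (1.18 ± 0.05) and the fractalkine receptor gene Cx3cr1 (1.17 ± 0.05), with a median of 0.86 (adjusted p = 4.41e-28). In RNA of whole hippocampus, list values cannot separate a change in cell number from a change per cell. All 19 reactive astrocyte genes rose, led by Ggta1 (1.64 ± 0.07), Gfap and the cytokine receptor gene Osmr (1.72 ± 0.08), with a median of 1.55. All 15 antigen presentation genes rose (median 1.58; B2m 1.68, H2-D1 1.84, H2-K1 1.60), and so did all 22 interferon response genes (median 1.17; Trim30a 1.33, Ifit3 1.60, Ifit3b 1.36). In the complement list 13 of 16 rose, including the C1q chains C1qa (2.32 ± 0.08), C1qc (2.13) and C1qb (2.08), and in the lysosome list 24 of 25 (25 adjusted over the list alone), including Ctss (2.08) and Laptm5 (1.76). Of 19 cholesterol synthesis genes 18 rose by little (median 0.31; Fdps 0.55, Nsdhl 0.54, Mvd 0.60). Orthologues of Alzheimer risk loci went both ways, 13 of 23 rising (Trem2, Apoe, Inpp5d 1.06) and 4 falling, among them Ptk2b (-0.23 ± 0.03) and Sorl1 (-0.19 ± 0.04). In the general astrocyte list 10 of 16 rose (12 adjusted over the list alone; S100b 0.50, Aqp4 0.97, Aldh1l1 0.41). These calls all held with an estimated correlation (adjusted p up to 0.0479 for cholesterol synthesis). So did the T cell list (4 of 6, 5 adjusted over the list alone), in which Thy1, a transgene-affected row, comes first, followed by the chemokine gene Ccl5 (1.2 ± 0.12) and Trac (0.35 ± 0.11).

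Neuronal lists fell by smaller amounts at 14 months, and none of their calls held with an estimated correlation. Of 16 excitatory neuron genes 15 fell, first Itpka (-0.34 ± 0.04), the AMPA receptor gene Gria1 (-0.29 ± 0.04) and Neurod6 (-0.24 ± 0.04). The list median was -0.16 (adjusted p = 0.000209, adjusted p = 0.147 with an estimated correlation). Of 20 synaptic genes 19 fell, including Syt1 (-0.27), the NMDA receptor gene Grin1 (-0.24) and Snap25 (-0.19), with adjusted p = 0.0947 with an estimated correlation. Inhibitory neuron genes fell in 11 of 16 (Gad1 -0.33, Sst -0.40; adjusted p = 0.227 with an estimated correlation). Hippocampal subfield genes fell in 10 of 16 (Pou3f1 -0.45, Fibcd1 -0.51, Man1a -0.28; adjusted p = 0.265 with an estimated correlation). Activity-dependent genes fell in 12 of 20 (Fosl2 -0.34, Nr4a1 -0.50, Nr4a2 -0.45; adjusted p = 0.64 with an estimated correlation). Oxidative phosphorylation genes fell in 16 of 24 and 1 rose (Ndufs1 -0.16, Uqcrc2 -0.17, Atp5a1 -0.12; adjusted p = 0.5 with an estimated correlation). Myelin genes rose in 11 of 18 (12 adjusted over the list alone; Trf 0.91, Cldn11 0.51, Gjb1 0.31; adjusted p = 0.389 with an estimated correlation). Oligodendrocyte precursor genes rose in 7 of 12 and 1 fell (Neu4 0.26, Gpr17 0.27, Lhfpl3 0.22; adjusted p = 0.227 with an estimated correlation). Peripheral myeloid genes rose in 4 of 9 (Ms4a7 0.66, Ly6c2 0.41, Cd163 0.23; adjusted p = 0.265 with an estimated correlation). Lists of neighbouring or vascular tissue gave no list call. Choroid plexus genes passed in 0 of 15 (median -0.05, camera direction up, adjusted p = 0.775), with Ttr at 5905 ± 3654 TPM in 5XFAD and 6252 ± 4328 TPM in Ntg. Haemoglobin and other blood genes fell in 4 of 5 (median -0.51, adjusted p = 0.301). Mural genes rose in 3 of 11 (adjusted p = 0.214), and 1 endothelial gene rose and 1 fell of 15 (1 and 0 adjusted over the list alone; adjusted p = 0.463). Striatum markers fell in 3 of 12 (adjusted p = 0.617). Thalamus markers rose in 4 and fell in 2 of 12 (adjusted p = 0.372), and the X and Y genes passed in 0 of 5 (adjusted p = 0.609).

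**Figure D2:**
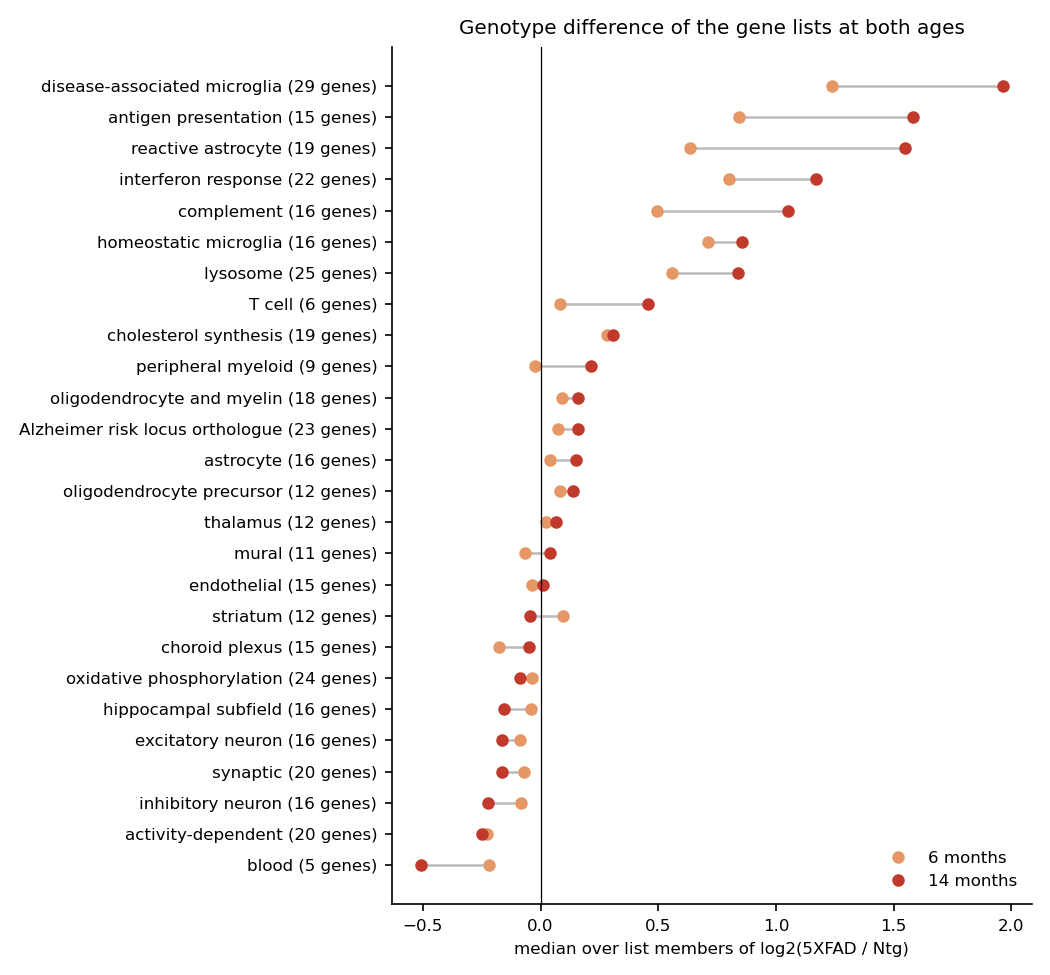
Median log2 difference (5XFAD / Ntg) over the measured members of each gene list at 6 months (light points) and 14 months (dark points), with a grey line joining the ages. The disease-associated microglia median moves from 1.24 to 1.96 and the reactive astrocyte median from 0.63 to 1.55, while the blood list lies lowest at -0.51 at 14 months.

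At 6 months microglial genes led again, with 7 of the 10 leading genes shared. Cst7 averaged 67.6 ± 43.9 TPM (SD, n = 33) in 5XFAD and 0.641 ± 1.81 TPM (n = 31, and 0.318 TPM without the highest library) in Ntg (5.08 ± 0.23, adjusted p = 3.68e-40), and Trem2 99.7 ± 45.6 against 18.2 ± 3.67 TPM (2.24 ± 0.09). The genes next to Cst7 were Clec7a (3.15 ± 0.13), Ccl3 (2.5 ± 0.11), Ccl6 (2.48 ± 0.12), Cd52 (2.47 ± 0.13) and Itgax (2.44 ± 0.13). Lyz2 (2.26 ± 0.14), Tyrobp (2.21 ± 0.09) and the survival gene Bcl2a1b (2.11 ± 0.12) rose as well. The prohormone convertase gene Pcsk1 fell from 15.8 ± 6.90 to 10.7 ± 2.6 TPM (-0.46 ± 0.09, adjusted p = 1.43e-05). The other lowest genes were Ptges3-ps (-1.26 ± 0.32), Prickle4 (-0.57 ± 0.17), Btg3 (-0.47 ± 0.17, adjusted p = 0.0352) and the mitochondrial gene mt-Co3 (-0.39 ± 0.15, adjusted p = 0.0484), the last 2 losing their call under several alternatives. In all, 3259 genes passed, 1295 higher and 1964 lower, 90 and 2 of them over 2-fold, and median-ratio scaling gave 1570 higher and 1383 lower. With strain as the replicate 1627 genes passed. Of the genes higher at 6 months, 1241 were also higher at 14 months (206 if the calls were independent), 1793 were lower at both (602 if independent), and 1 went opposite ways.

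Apart from the peripheral myeloid list (0 of 9), the immune lists called at 14 months were called at 6 months too, with fewer members in several. Disease-associated microglia genes rose in 27 of 29 (median 1.24; Tyrobp, Clec7a and Trem2 first), homeostatic microglia genes in 14 of 16 (median 0.71; Siglech 1.02, Gpr34 0.95) and interferon response genes in 22 of 22 (median 0.80; Trim30a 0.94, Ifit3 1.13, Ifi27l2a 1.88). Antigen presentation genes rose in 15 of 15 (B2m 1.2, H2-D1 1.18, Psmb8 1.07) and lysosome genes in 21 of 25 (23 adjusted over the list alone; Ctss 1.62, Grn 0.91). Complement genes rose in 10 of 16 (11 adjusted over the list alone; C1qa 1.62, Itgb2 1.44, C1qc 1.54), reactive astrocyte genes in 12 of 19 (13 adjusted over the list alone; Gfap 1.46, Ggta1 0.88, Aspg 1.00) and cholesterol synthesis genes in 18 of 19 (Fdps 0.47, Fdft1 0.43, Nsdhl 0.42). Risk locus orthologues rose in 10 of 23 and fell in 2 (12 and 2 adjusted over the list alone; Trem2, Abi3 1.06, Inpp5d 0.79), and in the T cell list Thy1 and Ccl5 (0.57) rose, 2 of 6, and this list was not tested without the transgene-affected row. These 10 calls held with an estimated correlation (adjusted p up to 0.0072). The other 8 did not, with adjusted p from 0.204 to 0.701. Among them activity-dependent genes fell in 7 of 20 (9 adjusted over the list alone; the growth factor gene Bdnf -0.20, Fosl2 -0.28, Nr4a2 -0.34) and synaptic genes in 9 of 20 (11 adjusted over the list alone; Homer1 -0.32, Syt1 -0.16, Snap25 -0.11). Excitatory neuron genes fell in 4 of 16 (Itpka -0.16, Grin2a -0.17, Neurod6 -0.12) and inhibitory neuron genes in 5 of 16 (7 adjusted over the list alone; Vip -0.24, Gad1 -0.15, Erbb4 -0.20). Astrocyte genes rose in 7 of 16, myelin genes in 4 of 18 (5 adjusted over the list alone) and precursor genes in 2 of 12 with 1 falling, while oxidative phosphorylation genes fell in 4 of 24 (5 adjusted over the list alone). Choroid plexus and blood genes passed in 0 of 15 and 0 of 5.

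The question of the age interaction was whether the genotype difference itself changed between 6 and 14 months. It grew for Spp1 by 2.10 ± 0.23 on the log2 scale (adjusted p = 3.45e-12). Spp1 averaged 136.1 ± 60.7 TPM in 5XFAD and 17.4 ± 8.73 TPM in Ntg at 14 months, but 27.5 ± 16.9 and 16.3 ± 9.61 TPM at 6 months. The protease gene Klk6 (1.96 ± 0.17, adjusted p = 1.6e-16) went from 4.13 ± 1.70 TPM in 5XFAD at 6 months to 24.8 ± 16.8 TPM at 14 months, and the glycoprotein gene Gpnmb (1.84 ± 0.14, adjusted p = 1.33e-20) from 6.17 ± 4.79 to 30.5 ± 14.8 TPM. The difference also grew for class II genes, H2-Aa (1.98 ± 0.30), H2-Eb1 (1.66 ± 0.30), Cd74 (1.64 ± 0.33), H2-Ab1 (1.32 ± 0.26) and the pseudogene H2-Ea-ps (1.24 ± 0.30), and for Itgax (1.29 ± 0.17) and Cst7 (1.24 ± 0.32). The difference became more negative for Frat1 (-0.68 ± 0.19), Ndst4 (-0.50 ± 0.09), Ankrd63 (-0.46 ± 0.12), the substance P gene Tac1 (-0.39 ± 0.12) and the nicotinic receptor gene Chrna5 (-0.37 ± 0.09). On GRCm38, Spp1 (ENSMUSG00000029304) lies on chromosome 5 from 104435118 to 104441050 and Klk6 (ENSMUSG00000050063) on chromosome 7 from 43824499 to 43832030. In all, 1042 genes passed, 717 with a higher and 325 with a lower difference at 14 months, but 146 without the B6 and D2 libraries.

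The lists whose genotype difference grew and kept the call with an estimated correlation (adjusted p up to 0.0155) were reactive astrocyte, disease-associated microglia, antigen presentation, complement, lysosome and astrocyte. Reactive astrocyte genes grew in 15 of 19 (18 adjusted over the list alone; S1pr3 0.95, Serpina3n 1.17, S100a6 1.09; median 0.79). Disease-associated microglia genes grew in 21 of 29 (24 adjusted over the list alone; Gpnmb, the heparanase gene Hpse 1.2, Spp1; median 0.50). Antigen presentation genes grew in 13 of 15 (15 adjusted over the list alone; H2-Aa, H2-Eb1, H2-D1 0.67) and complement genes in 12 of 16 (13 adjusted over the list alone; C3 1.15, C1qa 0.70, C1qc 0.59). Lysosome genes grew in 16 of 25 (21 adjusted over the list alone; Ctsh 0.56, Ctsb 0.29, Lamp1 0.21) and astrocyte genes in 6 of 16 (9 adjusted over the list alone; the water channel gene Aqp4 0.59, S100b 0.27, Slc1a3 0.22). Calls for 14 other lists were lost, with adjusted p from 0.0919 to 0.582 with an estimated correlation. Among these, interferon response genes grew in 7 of 22 (10 adjusted over the list alone; median 0.30) and homeostatic microglia genes in 6 of 16 (9 adjusted over the list alone; median 0.16). Synaptic differences became lower in 5 of 20 (13 adjusted over the list alone; Grin1 -0.15, Rab3a -0.14, Cplx2 -0.13). Inhibitory neuron differences became lower in 4 of 16 (7 adjusted over the list alone; Sst -0.26, Lhx6 -0.18, Gad1 -0.18) and excitatory neuron differences in 2 of 16 (7 adjusted over the list alone; Gria1 -0.20, Itpka -0.18). Cholesterol synthesis genes passed in 0 of 19 and choroid plexus genes in 0 of 15.

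In Ntg mice, age changed fewer genes and by less. The complement gene C4b rose from 24.4 ± 7.64 (n = 31) at 6 months to 39.6 ± 7.86 TPM (n = 33) at 14 months (0.72 ± 0.11, adjusted p = 4.38e-06), and C3 rose by 0.59 ± 0.10. Spag6, an axoneme gene, rose from 2.84 ± 1.00 to 4.88 ± 1.07 TPM (0.66 ± 0.07, adjusted p = 5.43e-13). The immunoglobulin gene Igkc (1.07 ± 0.35, adjusted p = 0.0497), Cox8b (0.96 ± 0.31) and the endothelial gene Apold1 (0.73 ± 0.11) rose too. So did Vgll3 (0.68 ± 0.14), the thyroid hormone deiodinase gene Dio3 (0.58 ± 0.14), Lyz2 (0.55 ± 0.14) and Depp1 (0.52 ± 0.13). The lowest were Sh2d1a (-0.62 ± 0.17), the hypoxia factor gene Hif3a (-0.40 ± 0.10), the axon guidance gene Robo3 (-0.38 ± 0.11), Pcdhgc4 (-0.37 ± 0.09) and Gpr17 (-0.34 ± 0.05, adjusted p = 1.71e-06), a receptor of maturing oligodendrocyte precursors that went from 19.1 ± 3.30 to 14.7 ± 1.51 TPM. In all, 954 genes passed, 856 higher and 98 lower at 14 months, but 451 higher and 295 lower with median-ratio scaling and 510 and 210 with quantile scaling. The count fell to 355 with choroid plexus and myelin covariates and also without B6 and D2, to 465 with no strain term and to 493 without the 7 doubted libraries. The camera test called 11 lists, none of them with an estimated correlation (adjusted p of at least 0.713). Cholesterol synthesis genes rose in 10 of 19 (18 adjusted over the list alone; Srebf2 0.16). Inhibitory neuron genes rose in 6 of 16 (9 adjusted over the list alone; Cnr1 0.16, Gad1 0.15) and myelin genes in 6 of 18 (8 adjusted over the list alone; Myrf 0.22, Trf 0.29, Gjb1 0.26). Activity-dependent genes rose in 3 of 20 (11, with 1 falling, adjusted over the list alone; Sik1 0.38, Fosl2 0.26, Dusp1 0.32). Complement genes rose in 3 of 16 (5 adjusted over the list alone) and disease-associated microglia genes in 3 of 29 (4 adjusted over the list alone; Lyz2, Timp2 0.28, Csf1 0.13). Choroid plexus genes passed in 0 of 15 although their median was 0.56 (camera adjusted p = 0.0538), and blood genes in 0 of 5 (median 0.38, adjusted p = 0.0811). With median-ratio scaling the camera test also called choroid plexus (adjusted p = 0.00239), blood (0.0221) and interferon response (0.0129). Over all alternatives these ran from 0.0019, 0.0132 and 0.0129 to 0.781, 0.713 and 0.781.

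In 5XFAD mice the age difference was larger. Spp1 (2.30 ± 0.16, adjusted p = 8.38e-25), Klk6 (2.17 ± 0.12), Gpnmb (2.12 ± 0.10, adjusted p = 6.37e-39) and H2-Aa (2.06 ± 0.21) rose most. Cd74 (1.99 ± 0.23), H2-Eb1 (1.94 ± 0.21), C3 (1.74 ± 0.09, adjusted p = 2.9e-32), H2-Ab1 (1.69 ± 0.18), Cst7 (1.53 ± 0.22) and C4b (1.49 ± 0.11) followed. C4b went from 90.7 ± 47.2 (n = 33) to 223 ± 48.8 TPM (n = 36). The lowest were Gdf1 (-0.77 ± 0.28), Sh2d1a (-0.59 ± 0.17), Kirrel2 (-0.55 ± 0.07), Hif3a (-0.49 ± 0.10) and the tryptophan dioxygenase gene Tdo2 (-0.48 ± 0.09). In all, 4327 genes passed, 2816 higher and 1511 lower, against 2704 and 2251 with median-ratio scaling and 2322 and 2940 with quantile scaling, and 2528 genes passed without B6 and D2. All 19 reactive astrocyte genes rose (Ggta1 1.04, Osmr 1.15, S1pr3 1.09; median 1.04), as did 27 of 29 disease-associated microglia genes (28 adjusted over the list alone) and 25 of 25 lysosome genes (Lamp1 0.28, Ctsb 0.35, Ctsh 0.62). Rises were also called in 15 of 15 antigen presentation genes (H2-D1 0.90, H2-K1 0.85, H2-Aa) and 13 of 16 complement genes (14 and 1 falling adjusted over the list alone). They were called in 14 of 16 homeostatic microglia genes, 11 of 16 astrocyte genes (12 adjusted over the list alone) and 13 of 23 risk locus genes with 1 falling (14 and 1 adjusted over the list alone). Excitatory neuron genes fell in 10 of 16 (the calmodulin-binding gene Nrgn -0.20, Itpka -0.22, Neurod2 -0.21; median -0.15). These 9 list calls held with an estimated correlation (adjusted p up to 0.0389), while 9 others did not (adjusted p from 0.109 to 0.553). Among the latter, 19 of 19 cholesterol synthesis genes rose, as did 20 of 22 interferon response genes (21 adjusted over the list alone). In the same way 12 of 18 myelin genes rose (14 adjusted over the list alone; Trf 0.71, Gjb1 0.39, Ermn 0.34) and 7 of 20 activity-dependent genes rose (8 adjusted over the list alone; Fos 0.67, Egr2 0.51, Klf4 0.22). Of the synaptic genes 11 of 20 fell (Grin1 -0.16, Dlg4 -0.14, Syp -0.10), and of the hippocampal subfield genes 7 of 16 (Calb1 -0.23, Pou3f1 -0.34, Tdo2). Choroid plexus genes had a median of 0.72 and passed in 0 of 15 (adjusted p = 0.0613), and with median-ratio scaling this list was called (adjusted p = 0.0353, and from 0.0118 to 0.681 over the alternatives).

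Among 5XFAD mice, immune genes were higher in females. C3 averaged 8.43 ± 6.67 TPM (SD, n = 31) in females and 4.28 ± 3.07 TPM (n = 38) in males (0.78 ± 0.10, adjusted p = 3.4e-10), and Trem2 154.7 ± 43 against 119 ± 52.2 TPM (0.49 ± 0.09). Besides the X-linked silencing RNA Xist, the largest female excess was in the protease inhibitor gene A2m (0.88 ± 0.16), the chemokine gene Cxcl10 (0.84 ± 0.16) and the lipocalin gene Lcn2 (0.84 ± 0.15). The interferon-induced gene Ifi27l2a (0.83 ± 0.18), C3, Timp1 (0.73 ± 0.12), the chemokine gene Cxcl13 (0.73 ± 0.12), Cd52 (0.73 ± 0.12) and the interferon-induced gene Oasl2 (0.72 ± 0.12) followed. Apart from the Y-linked Eif2s3y, Ddx3y, Kdm5d and Uty, the lowest was Xlr3b (-0.71 ± 0.19). In all, 2759 genes passed, 1158 higher and 1601 lower in females, but 1599 higher and 852 lower with median-ratio scaling. The count was 981 without B6 and D2 and 1783 with averaged cells. Disease-associated microglia genes were higher in 25 of 29 (26 adjusted over the list alone; Gpnmb 0.72, Cd180 0.55, Csf1 0.24; median 0.43) and interferon response genes in 20 of 22 (22 adjusted over the list alone; Ifit3 0.67, Oas1a 0.67, Oasl2). Complement genes were higher in 13 of 16 (C3, Itgam 0.44, Itgb2 0.51) and reactive astrocyte genes in 17 of 19 (Serpina3n 0.65, Ggta1 0.44, S1pr3 0.50). Homeostatic microglia genes were higher in 14 of 16 (15 adjusted over the list alone; Gpr34 0.56, Siglech 0.39, Olfml3 0.42) and lysosome genes in 21 of 25 (22 adjusted over the list alone). The same held for antigen presentation genes in 11 of 15 (14 adjusted over the list alone), astrocyte genes in 7 of 16 (9 adjusted over the list alone) and risk locus genes in 11 of 23 with 2 lower (Inpp5d 0.40, Apoe 0.25, Ms4a6d 0.46). These calls held with an estimated correlation (adjusted p up to 0.0198). Excitatory neuron genes were lower in 5 of 16 (12 adjusted over the list alone; Itpka -0.18, Kcnj4 -0.18, Tbr1 -0.17; adjusted p = 0.177 with an estimated correlation) and synaptic genes in 7 of 20 (11 adjusted over the list alone; Grin1 -0.15, Camk4 -0.16, Rab3a -0.09; adjusted p = 0.24 with an estimated correlation). Another 6 list calls were lost with an estimated correlation, with adjusted p from 0.0681 to 0.582. Choroid plexus genes passed in 0 of 15 (median 0.08, adjusted p = 0.241).

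Among Ntg mice 36 genes differed between the sexes, 22 higher and 14 lower in females. They included Xist, the X-linked Eif2s3x (0.56 ± 0.03, adjusted p = 1.85e-36), Kdm6a (0.44 ± 0.04), Kdm5c (0.38 ± 0.04) and Ddx3x (0.33 ± 0.03), and the Y-linked Eif2s3y, Ddx3y, Kdm5d and Uty. The other named genes were A2m (0.74 ± 0.16), at 5.75 ± 4.14 (n = 34) against 2.75 ± 1.26 TPM (n = 30), the pseudogene rows Pisd-ps1 (0.55 ± 0.08) and Pisd-ps2 (0.53 ± 0.07), Cpxm2 (0.48 ± 0.11), the retinol transporter gene Stra6 (0.42 ± 0.07) and the cold-shock gene Rbm3 (-0.31 ± 0.07). No disease-associated microglia gene passed (0 of 29 in limma; smallest p for Gpnmb, 0.29 ± 0.10, and Ccl3, 0.26 ± 0.11). The camera test called 9 lists, of which 1, the X and Y genes, was called with an estimated correlation. The others included choroid plexus (median 0.48, adjusted p = 0.00172) and disease-associated microglia (median 0.07, adjusted p = 0.00284), each with adjusted p = 0.871 with an estimated correlation.

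The sex difference itself differed between genotypes in 311 genes, 217 with a larger and 94 with a smaller female excess in 5XFAD, against 405 and 45 with median-ratio scaling and 289 and 250 with choroid plexus and myelin covariates. Lcn2 led (0.97 ± 0.22, adjusted p = 0.00838), with 5.69 ± 4.42 TPM in female and 2.73 ± 2.27 TPM in male 5XFAD mice and 0.553 ± 0.506 and 1.12 ± 2.77 TPM in Ntg females and males (males 0.664 TPM without the highest library). The metabolite receptor gene Hcar2 (0.68 ± 0.11, adjusted p = 0.000112) had 3.70 ± 2.10 and 1.95 ± 1.31 TPM in the 5XFAD sexes and 0.115 ± 0.0996 and 0.107 ± 0.106 TPM in the Ntg sexes. Oasl2 (0.80 ± 0.17), the antibody receptor gene Fcgr4 (0.70 ± 0.13), S100a4 (0.70 ± 0.18), Klk6 (0.69 ± 0.17), Timp1 (0.66 ± 0.18), the transglutaminase gene Tgm1 (0.65 ± 0.13), Cxcl13 (0.65 ± 0.18) and Ly9 (0.63 ± 0.14) were among the largest as well. The lowest were Fndc8 (-0.36 ± 0.10), the kinase gene Wnk4 (-0.34 ± 0.10), Pisd-ps2 (-0.32 ± 0.09), Nle1 (-0.30 ± 0.07) and the fibrillin gene Fbn1 (-0.28 ± 0.07). On GRCm38, Lcn2 (ENSMUSG00000026822) lies on chromosome 2 from 32384633 to 32388252 and Hcar2 (ENSMUSG00000045502) on chromosome 5 from 123863570 to 123865499. Without the B6 and D2 libraries 4 genes passed, and Hcar2 was the only named gene among them. Lists held with an estimated correlation were complement with 7 of 16 members (13 adjusted over the list alone; C3 0.62, Itgam 0.36, Itgb2 0.39), homeostatic microglia with 8 of 16 (13 adjusted over the list alone; Gpr34 0.47, Siglech 0.39) and reactive astrocyte with 7 of 19 (15 adjusted over the list alone; Vim 0.60, Lcn2, S1pr3 0.47). Interferon response with 6 of 22 (17 adjusted over the list alone; Oasl2, Ifit3 0.59, Oas1a 0.55) and disease-associated microglia with 4 of 29 (18 adjusted over the list alone; Cd180 0.53, Cd84 0.53, Axl 0.21) held too, with adjusted p up to 0.0269 over these 5. The other 15 calls were lost, with adjusted p from 0.0646 for lysosome (6 of 25, 15 adjusted over the list alone) to 0.593 with an estimated correlation. Blood genes had a median of -0.49 and choroid plexus genes of -0.36, with 0 members passing in each.

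**Figure D3:**
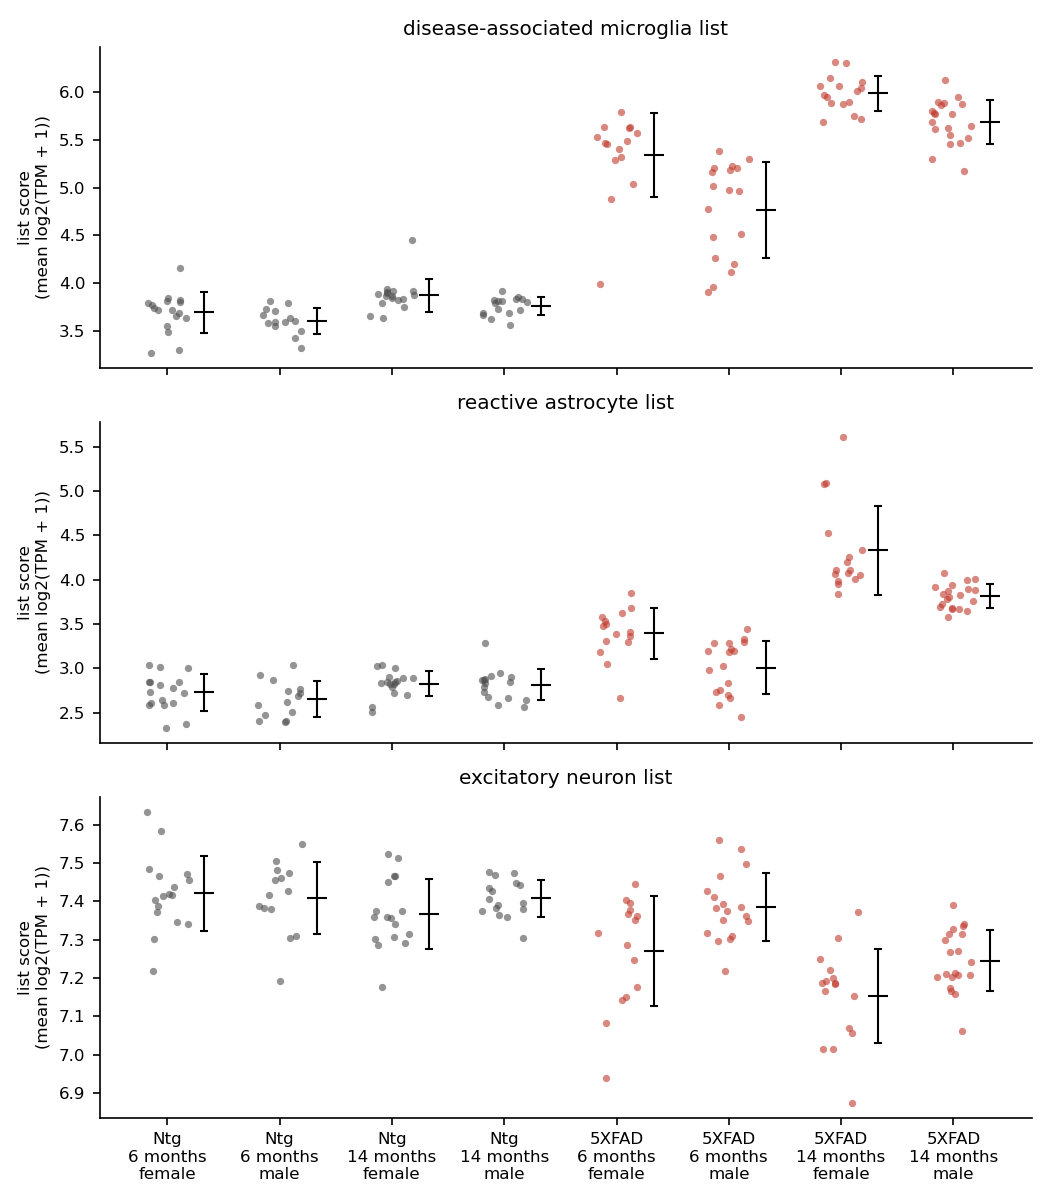
Scores of the disease-associated microglia, reactive astrocyte and excitatory neuron lists (mean log2(TPM + 1) over members) in single libraries (points) of the 8 groups, with mean ± SD beside each. In 5XFAD mice the disease-associated microglia score averages 5.99 in females and 5.69 in males at 14 months and 5.34 and 4.77 at 6 months, against 3.61 to 3.87 in the Ntg groups.

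D2 and B6 libraries differed most in rows for pseudogenes, paralogs and a haemoglobin gene, where a variant or reads placed on a related sequence can shift the value. Rpsa-ps10, a copy of the ribosomal protein gene Rpsa, averaged 434 ± 42.8 TPM (SD, n = 25) in D2 and 5.85 ± 15.4 TPM (n = 18) in B6 (7.03 ± 0.23, adjusted p = 7.91e-53; B6 2.24 TPM without its highest library), while Rpsa averaged 223 ± 17.6 and 429 ± 23.7 TPM. Hba-a1 averaged 3.62 ± 2.82 TPM in D2 and 187 ± 71.6 TPM in B6 (-5.58 ± 0.26, adjusted p = 3.34e-39), whereas its paralog Hba-a2 had 470 ± 218 and 319 ± 110 TPM and did not pass. Tpm3-rs7 (4.53 ± 0.09), Rpl38-ps2 (104.01 ± 43.01 TPM, and 0 TPM in B6), n-R5-8s1 (5.24 ± 0.28) and Rpl36-ps12 (2.69 ± 0.20) were higher in D2. So were the serpin gene Serpina3h (2.19 ± 0.14), H2-Ea-ps (2.19 ± 0.26), the ATP synthase gene Atp5g2 (1.94 ± 0.06), Prss41 (1.70 ± 0.08) and Hbq1a (1.48 ± 0.14). Ppp1ccb (-4.60 ± 0.32), Nat8f4 (-1.98 ± 0.06, adjusted p = 3.99e-57), Fggy (-1.56 ± 0.09) and Rpl39-ps (-1.43 ± 0.21) were lower. In all, 2678 genes passed, 1251 higher and 1427 lower in D2, but 1806 higher and 1080 lower with choroid plexus and myelin covariates, and 878 genes with averaged cells. On GRCm38, Rpsa-ps10 (ENSMUSG00000047676) lies on chromosome 3 from 150072658 to 150073542 and Hba-a1 (ENSMUSG00000069919) on chromosome 11 from 32283511 to 32284465. None of the 11 list calls held with an estimated correlation (adjusted p of at least 0.536). All 18 myelin genes were lower in D2, Mobp (-0.46 ± 0.07), Mal (-0.46 ± 0.08) and Mog (-0.38 ± 0.07) first, with Mobp at 590 ± 128.9 against 810 ± 141 TPM. In the homeostatic microglia list 9 of 16 genes were lower (12 adjusted over the list alone; Fcrls -1.05, Slc2a5 -0.60, Selplg -0.38). In the disease-associated list 12 of 29 genes were lower and 1 higher (17 and 1 adjusted over the list alone; Gpnmb -0.99, Csf1 -0.28, and the lipase gene Lpl 0.30). Values were lower for 10 of 25 lysosome genes (12 adjusted over the list alone), 6 of 16 complement genes (9 adjusted over the list alone; C1qb -0.66, C1qc -0.66, C5ar1 -0.39) and 6 of 22 interferon response genes (12 adjusted over the list alone). The blood call rested on Hba-a1, with a median of -0.21 and a mean of -1.23. Antigen presentation had a median of -0.03 and a mean of 0.05 (adjusted p = 0.603).

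Over all strain labels, 5970 genes differed. The smallest p were those of Tpm3-rs7 (adjusted p = 3.17e-98), the acetyltransferase-like gene Nat8f4 (3.46e-77), Rpsa-ps10, Rpsa, Atp5g2, Rps7, the secretory granule gene Scg5, Rpl5, Rpl21 and the glyoxalase gene Glo1 (1.08e-54). Glo1 averaged 174 ± 12.9 TPM in D2 and 123 ± 8.33 TPM in B6. The strain by genotype test asked whether the genotype effect depended on the strain, and 2 genes passed. Ctse, an aspartic protease gene, had adjusted p = 1.08e-07 and Fcrls, a microglial receptor gene, 5.32e-05, and 520 genes had an unadjusted p below 0.05. The Ctse call depends on the pseudocount, with adjusted p = 1 at 0.1 and from 2.26e-10 to 1 over the alternatives, and its Ntg values lie near 0. Fcrls passed in every alternative run for this test (adjusted p up to 0.00037), none of which left out the B6 label. At 14 months Ctse in 5XFAD mice averaged 17.3 TPM (n = 2) in strain 32, 16.8 (n = 3) in 44, 13.7 (n = 2) in 68, 13.02 (n = 2) in 65 and 12.8 ± 5.37 (n = 6) in D2, and between 1.15 and 2.38 TPM in the other 9 strains. Among Ntg mice at 14 months Ctse was also higher in those named strains, at least 0.335 TPM against at most 0.229 TPM in the other 9. A strain difference present in both genotypes is thus part of the Ctse pattern. At 6 months Ctse in D2 5XFAD mice averaged 3.29 ± 3.37 TPM (n = 7). Fcrls in 5XFAD mice at 14 months was lowest in strain 68 (15.8 TPM, n = 2) and D2 (26.3 ± 13.2 TPM, n = 6) and highest in strains 66 (93.3 TPM, n = 2) and 61 (91.5 TPM, n = 2). Ntg means of Fcrls at that age were 11.7 TPM in strain 68, 10.9 in D2, 21.1 in 66 and 17.4 in 61. Within B6, Fcrls ran from 17.9 to 84.9 TPM in 5XFAD (n = 10) and from 19.4 to 21.6 TPM in Ntg libraries (n = 8). B6 5XFAD libraries at 71.2 TPM or more, 1 of them a male, had lower numbers in their titles than those at 36.3 TPM or less. Strain label alone therefore does not account for Fcrls in 5XFAD mice, and the cause of this split was not tested. Ctse (ENSMUSG00000004552) lies on chromosome 1 from 131638306 to 131675505 and Fcrls (ENSMUSG00000015852) on chromosome 3 from 87250758 to 87263738.

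**Figure D4:**
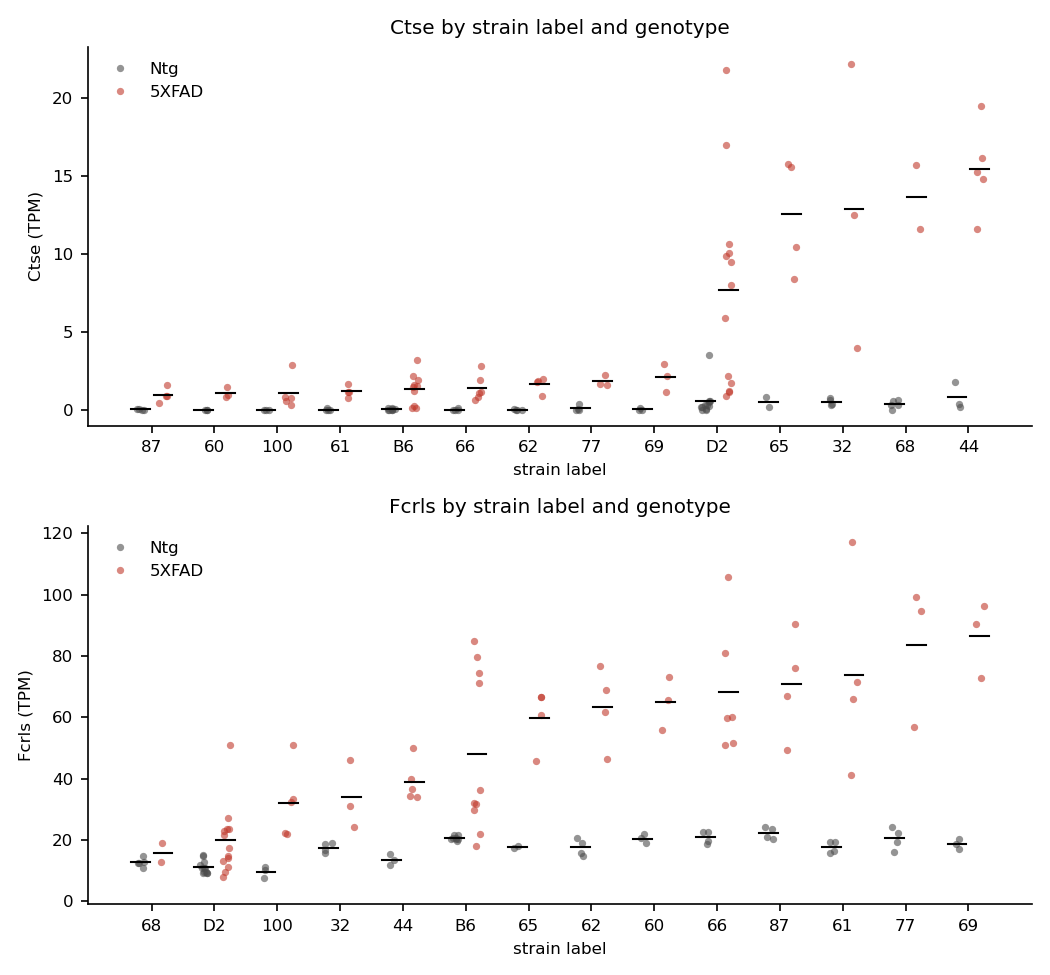
Ctse and Fcrls (TPM) in single Ntg (grey) and 5XFAD (red) libraries by strain label, with short bars at means and the strain label with 1 library left out. Both ages are pooled, in shares that differ between strains, and strain 68 has 14-month 5XFAD libraries alone.

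By strain, the genotype difference of the disease-associated microglia score was positive everywhere it could be measured. At 14 months it ran from 1.81 to 2.32 over 14 strains (median 2.02) and at 6 months from 0.773 to 2.09 over 13 (median 1.68). The lowest value at 14 months was that of D2, whose Ntg females include replicate 4, with human APP and a score of 4.45. Other D2 Ntg females of that age had 3.64 and 3.94. In strain 44 at 6 months (difference 1.52), Ntg female replicate 2 carried human APP as well. By-strain differences were not computed without these libraries. At 6 months strains 32, 60, 69 and 77 had 1 5XFAD library each, a male in strain 32 and females in the others. The highest value, 2.09 in strain 77, rests on 1 female, so sex and single libraries add to this spread. The reactive astrocyte difference ran from 0.851 to 1.76 and from 0.186 to 1.06. The excitatory neuron difference was negative in all 14 strains at 14 months, between -0.312 and -0.068, and positive in 1 of 13 at 6 months. That positive value was for strain 69, with 1 library of each genotype at 6 months. Choroid plexus differences spread from -2.45 to 2.96 and from -3.41 to 2.75. No list of 26 differed among strains in its genotype effect after adjustment (permutation test of F; disease-associated microglia F = 1.74, p = 0.0682, adjusted p = 0.906).

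**Figure D5:**
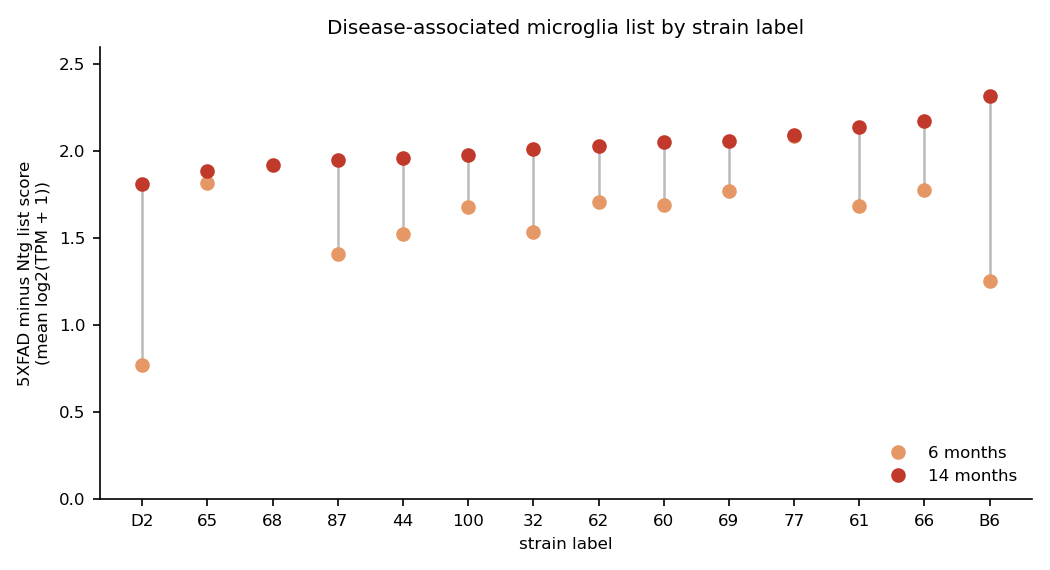
5XFAD minus Ntg difference of the disease-associated microglia score (mean log2(TPM + 1)) for each strain label at 6 (light points) and 14 months (dark points), ordered by the value at 14 months. Differences run from 0.773 to 2.09 at 6 months and from 1.81 to 2.32 at 14 months, and strain 68 has no 6-month 5XFAD library. Ntg libraries with human APP are included. Strains 32, 60, 69 and 77 have 1 5XFAD library each at 6 months, and the highest value at that age, in strain 77, rests on 1 female.

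Over strains, 9 relations among human APP and list scores of 5XFAD libraries at the 2 ages were computed, with Ntg values not subtracted. Strain labels did not differ detectably in human APP over both ages (F = 1.08, permutation p = 0.398). Human APP and the scores of an age were means of the same libraries. Relations between them can therefore reflect differences between single libraries, and do not show an effect of strain. At 6 months human APP was related to the disease-associated microglia score (r = 0.713, permutation p = 0.00573, rho = 0.709, permutation p = 0.00945, adjusted p = 0.0409), with r = 0.404 without the 2 strains farthest from the median human APP. With Ntg scores subtracted r was 0.528 (adjusted p = 0.278, and from 0.019 to 0.278 over the alternatives). At 14 months human APP was related to the reactive astrocyte score by r (0.696, permutation p = 0.00909, adjusted p = 0.0409) but not by rho (0.345, permutation p = 0.227), and this rests on 2 strains, since r was 0.0604 without them (adjusted p from 0.0387 to 0.267 over the alternatives). Human APP and the reactive astrocyte score at 6 months gave r = 0.582 (permutation p = 0.0383, rho = 0.604, permutation p = 0.0328, adjusted p = 0.115), and r = 0.0867 without 2 strains. Human APP and the microglia score at 14 months gave r = 0.446 (permutation p = 0.111, rho = 0.011, permutation p = 0.976, adjusted p = 0.25), and r = -0.446 without 2 strains. The excitatory neuron score gave r = -0.247 at 6 months (permutation p = 0.418, rho = -0.143, permutation p = 0.645) and r = -0.0989 at 14 months (permutation p = 0.736, rho = 0.138, permutation p = 0.639), with r = -0.268 and 0.673 without 2 strains. The 6-month and 14-month scores gave r = 0.0959 for disease-associated microglia (permutation p = 0.741, rho = 0.0714, permutation p = 0.822), 0.107 for reactive astrocyte (permutation p = 0.718, rho = 0, permutation p = 1) and 0.415 for excitatory neuron genes (permutation p = 0.159, rho = 0.231, permutation p = 0.447). Without 2 strains these became -0.558, -0.345 and -0.23, and adjusted p over these 5 relations ran from 0.286 to 0.741.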

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

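The tests of a wrong genotype label and of RNA from another strain in the Ntg libraries, and those of dissection and scaling for the sex difference, were chosen only after the result was seen. Groups held more than 10 libraries, so single samples far from their group were not tested for.

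Human APP stood above the level of the other Ntg libraries in 4 of them, all female, a signal in samples that should carry no transgene. These were the 6-month Ntg female replicate 2 (strain 44, 137.3 TPM) and the 14-month Ntg female replicates 4 (D2, 215.1 TPM), 5 (B6, 105.6 TPM) and 17 (strain 51, 69.7 TPM), against at most 7.28 TPM in the other 60. The highest of the 4, 215.139 TPM, lay below the lowest 5XFAD library at 590 TPM, which argues against a 5XFAD mouse with an Ntg label. Both values were known when this cut was set, so it is not a test that excludes one. RNA or reads of 5XFAD libraries mixed in stay open. The summed Cst7, Itgax, Clec7a and Ccl6 was above every other Ntg library of that age and sex in 2 of the 4 (19.1 against 6.44 TPM, and 34.7 against 7.76 TPM). In the others it was not (7.22 and 5.29 TPM). An average 5XFAD library of their age and sex, mixed in at their human APP level, would give 15.8 and 12.3 TPM. Both of these libraries carried some Ddx3y, and donors of another sex or age were not tried. The shortfall therefore does not argue against mixing.

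Mixing with RNA of a mouse of another strain label may be a source of the same libraries, and could not be decided: a shift toward another strain over about 10 genes lay above the other libraries of its own label in 2 of 3 testable libraries (26.9% against 15.4% for strain 44, 17.3% against 10.2% for B6, and 12.4% against 16.1% for D2). Among the 126 libraries of all labels that were not doubted, the highest shift was 34.6%. A first form of that test, on genes nearly absent from a label, gave 1 of 3 (76.9% for strain 44, 0 for B6, and no gene for D2). It was judged void for having 7, 3 and 0 genes and replaced after this result was seen. Rpsa-ps10, singled out after its values were seen, had 67.1 TPM in the B6 library against at most 8.89 in 17 others, and 46.1 TPM in the strain 44 library against at most 1.73 in 7 others. In the D2 library it had 409.5 TPM, within the 334.5 to 542.2 TPM of 22 others. Tpm3-rs7, also looked at, had 4.73 TPM in the B6 library against at most 0.751, and 24.7 TPM in the D2 library against at least 26.1. In the strain 44 library it had 33.4 TPM, within 25.6 to 33.9. Sex genes were out of place in 5 libraries. The 6-month 5XFAD female replicate 5 had 2.02 TPM of Ddx3y, the 14-month Ntg female replicates 5 and 17 had 2.33 and 1.30 TPM, and the 14-month 5XFAD male replicate 3 had 16.1 TPM of Xist with 21.4 TPM of Ddx3y, whereas other females had at most 0.472 TPM of Ddx3y and other males at most 2.59 TPM of Xist. The 6-month Ntg female replicate 11 had 0.0643 TPM of Xist and 0 of Ddx3y. Of 8 libraries with neighbouring numbers in their titles, 6 failed one of these checks, against 1 of the other 125, but that range of numbers was drawn from failing libraries, which fixes part of the contrast. No biological explanation was tested.

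The disease-associated microglia score was higher in female than in male 5XFAD mice by 0.405 ± 0.0796 (SE), and the list's genotype difference was larger in females. With log2 human APP as a covariate the difference was 0.217 ± 0.0565, or 3.83 standard errors, so the measured level did not account for all of it. The difference became smaller, though, and a covariate measured with error leaves part of its effect behind. A large share may therefore go with the transgene level, and this test cannot exclude that level as the whole cause. With choroid plexus and myelin scores as covariates the difference was 0.380 ± 0.0777, or 4.89 standard errors. With median-ratio scaling it was 0.426 ± 0.0758, or 5.62 standard errors. The covariates left most of the difference and the scaling made it no smaller. Sex itself, as a biological difference acting beside or through the transgene, stays open and was not tested apart from it.

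Pseudogene copies were prominent in the D2 and B6 difference. If reads had only moved between a gene and its copy, the summed difference divided by the copy's own would be near 0, and with an unaffected parent gene near 1. Over 13 copies the median was 0.522501 (95% bootstrap interval 0.0314 to 1.57), with the parent opposite in sign in 8, so the 2 explanations cannot be told apart for these copies as a set. Single pairs lay near each expectation, Rpl38-ps2 with 103.4 TPM more and Rpl38 with -100.9 TPM in D2, and Bambi-ps1 with 1.37 TPM and Bambi with -0.0778 TPM. Strain variants at the copies could give either picture, and sequence reads, which would separate them, were not used here.

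The genotype effect differed between the ages in 1042 genes. Of 100 splits 1 gave as many, the real one, and the highest other gave 220. These splits shuffled age within genotype and sex, which removes the age effect in both genotypes along with its difference. They therefore cannot exclude chance for the interaction alone. The list medians of this difference were 0.79 for reactive astrocyte, 0.50 for disease-associated microglia, 0.48 for antigen presentation, 0.42 for complement, 0.28 for lysosome and 0.12 for astrocyte genes. Single genes had 2.10 (Spp1), 1.98 (H2-Aa), 1.96 (Klk6), 1.84 (Gpnmb), 1.66 (H2-Eb1), 1.64 (Cd74), 1.32 (H2-Ab1), 1.29 (Itgax), 1.24 (Cst7), 1.24 (H2-Ea-ps), -0.68 (Frat1), -0.50 (Ndst4), -0.46 (Ankrd63), -0.39 (Tac1) and -0.37 (Chrna5). Human APP was itself 261 TPM higher at 14 than at 6 months in 5XFAD mice, but 58.3 TPM without B6 and D2 (permutation p = 0.707).

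The genotype effect differed between the sexes in 311 genes (1 of 100 splits, highest other 5). Here sex was shuffled within genotype and age, which removes the sex effect too, so chance stays undecided for the interaction alone. The list medians were 0.43 for interferon response, 0.35 for complement, 0.33 for reactive astrocyte, 0.30 for disease-associated microglia and 0.25 for homeostatic microglia genes. Single genes had 0.97 (Lcn2), 0.80 (Oasl2), 0.70 (Fcgr4), 0.70 (S100a4), 0.69 (Klk6), 0.68 (Hcar2), 0.66 (Timp1), 0.65 (Tgm1), 0.65 (Cxcl13), 0.63 (Ly9), -0.36 (Fndc8), -0.34 (Wnk4), -0.32 (Pisd-ps2), -0.30 (Nle1) and -0.28 (Fbn1). The genotype effect differed among strains in 2 genes, Ctse and Fcrls, and for this count chance cannot be excluded, since 10 of 100 splits gave as many and the highest other gave 9.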

How the results depend on the processing

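The tests without the 4 Ntg libraries with human APP or the 7 doubted libraries, and the list tests with median-ratio scaling, were chosen only after the result was seen. Counts of called genes stayed within 1.5 times of their main value (given in the report) except as follows, and the cause was not tested apart from fewer libraries or genes. Without B6 and D2, which removes 43 libraries, 146 genes passed for genotype by age, 355 for age in Ntg, 2528 for age in 5XFAD, 981 for sex in 5XFAD, 18 for sex in Ntg and 4 for genotype by sex. With averaged cells the counts were 534 for genotype by age, 1783 for sex in 5XFAD, 126 for genotype by sex and 878 for D2 against B6. Strain as the replicate gave 1627 genes at 6 months. With no strain term 465 genes passed for age in Ntg and 20 for sex in Ntg. The covariates gave 355 for age in Ntg and 539 for genotype by sex. Without the 7 libraries 493 passed for age in Ntg. With no filter 187 passed for genotype by sex and 85 for strain by genotype, and with at least 5 TPM 1 passed for the latter. Leaving out each strain in turn gave 6991 (without B6) to 7867 genes at 14 months and 2441 (without strain 77) to 3354 at 6 months. With an estimated correlation, list calls went from 20 to 11 at 14 months, 18 to 10 at 6 months, 20 to 6 for genotype by age, 11 to 0 for age in Ntg, 18 to 9 for age in 5XFAD, 18 to 10 for sex in 5XFAD, 9 to 1 for sex in Ntg, 20 to 5 for genotype by sex and 11 to 0 for D2 against B6. No called list changed the sign of its median under quantile or median-ratio scaling. Quantile or median-ratio scaling lost the calls of activity-dependent and peripheral myeloid genes at 14 months, oxidative phosphorylation and inhibitory neuron genes at 6 months, and mural genes for age in 5XFAD. They also lost oxidative phosphorylation, peripheral myeloid and T cell genes for sex in 5XFAD, and oligodendrocyte precursor genes and the sex check for genotype by sex. Adjusted p of these lost calls lay between 0.0513 and 0.19 (0.000793 to 0.701 over all alternatives). Among the transgene tests, human APP at 14 minus 6 months was 58.3 TPM without B6 and D2 (permutation p = 0.707). Among the correlations, human APP with reactive astrocyte genes at 14 months gave r = 0.673 when standardised (adjusted p = 0.0503), 0.674 with Ntg values subtracted (0.0841) and 0.521 without B6 and D2 (0.267). Human APP with disease-associated microglia at 6 months gave 0.528 with Ntg values subtracted (0.278) and 0.541 without B6 and D2 (0.267). The sign reversed for reactive astrocyte genes at 6 against 14 months with Ntg values subtracted (-0.151) and, without B6 and D2, for human APP with disease-associated microglia (-0.0522) and with excitatory neuron genes (0.0422) at 14 months. The by-strain scores gave 0 of 26 lists under every alternative run. Of 2300 values of named genes under alternatives, 2159 kept direction and call, 141 kept direction alone and 0 reversed. No paired analysis was possible because the labels carry no numbers that pair libraries of 1 animal, and strain was used as a term, a block or the replicate. The depth is unknown, so what it limits cannot be stated.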

Other observations

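Choroid plexus content varied widely between libraries of a group. Ttr, the abundant transthyretin transcript of that tissue, had a standard deviation of 3654 TPM around a mean of 5905 TPM in 5XFAD libraries at 14 months, and the choroid plexus genotype difference of single strains ran from -2.45 to 2.96 at that age.

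Random regroupings of the libraries tested whether chance could give as many called genes. The following counts were each reached in 1 of 100 splits, the real one, so chance alone is an unlikely source of them. For sex in Ntg the called genes include Xist, Eif2s3x, Kdm6a, Kdm5c, Ddx3x, Eif2s3y, Ddx3y, Kdm5d and Uty, which are sex-linked. Only the real split can call them all, so it cannot decide on chance for the other genes called there. The counts were 7867 genes for genotype at 14 months (highest other split 1167), 3259 at 6 months (85), 954 for age in Ntg (1), 4327 for age in 5XFAD (718), 2759 for sex in 5XFAD (243), 36 for sex in Ntg (7), 2678 for D2 against B6 (186) and 5970 among strains (123).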
